A study of Rattus norvegicus with 12 samples.

How the data were processed

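Gene expression was measured in the ventricles of 12 rats, with 1 array per rat. Per the labels, total RNA was labelled with biotin, and the groups were rats with the left anterior descending coronary artery (LAD) occluded for 30 min and reperfused for 2 or 7 days (IR) and sham rats of the same days, with 3 rats in each of the 4 groups. The written study design names the 7 d sham group in 2 places and the 2 d sham group in none; the title and description of each sample give its day and its surgery, and groups were taken from these. Groups share no replicate numbers, and no pairing was used. The replicate numbers of the 7 d IR rats (44, 47 and 48) lie apart from those of the other 9 rats (69 to 82); the sources used here do not say what the numbers stand for or whether arrays were run in batches, so that no batch was fitted.

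The deposited values are an intensity per probe set on a linear scale, computed with MAS5 per the submitters' processing notes; its version and its detection calls are not given in the sources used here. MAS5 combines the perfect-match and mismatch probes of a probe set into a single signal. The mean of each array after leaving out 2% of the probe sets at each end was 1500.4 to 1500.5, so that the authors' intensity values had been scaled per array to a common level; a global scaling of this kind sets each array's mean and leaves differences in the shape of its distribution. Signals ran from 0.4 to 90742.8, and array medians from 637.3 to 719.0. No 2 arrays held identical values. The number of arrays limits the precision; arrays have no read depth.

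Signals were taken as log2(signal + 195), where 195 is the median over arrays of each array's 20th percentile. A fold change is therefore on the log2(signal + 195) scale, which understates changes of dim genes. Of 15923 probe sets, 57 controls were left out, and 10527 of the other 15866 lay above their array's 40th percentile in at least 3 arrays and were tested. Gene symbols came from GEO's platform annotation, in which 12789 probe sets have 1 gene symbol, 312 have several and 2822 are unnamed here; 12754 of the 12789 were found by their gene identifier in the RefSeq gene table of assembly GRCr8, and 0 symbols needed an update. Genes were named only from probe sets with 1 symbol. For a gene with several tested probe sets, the probe set with the highest mean log2 signal stands for it. This gave 8936 tested probe sets with 1 symbol and 7720 genes. No genome coordinates were used.

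A group-means model over all 12 arrays was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend), so that all groups share an estimate of the spread. The 6 comparisons were IR against sham at 2 d and at 7 d, the difference of these effects (interaction), their average, 7 d against 2 d sham, and 7 d against 2 d IR. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 10527 probe sets of a comparison, and an adjusted p under 0.05 was called. Log2 changes are given with limma's moderated standard error (SE). The overlap of calls at 2 d and 7 d was tested with Fisher's exact test over probe sets, which are not independent replicates. Single values per array were compared by exact two-sided permutation tests, which cannot go below 0.1 with 3 against 3 rats.

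Gene lists, 39 in all, were tested with limma's camera at a preset correlation of 0.01 between genes, and also with an estimated correlation and with fry, each adjusted over the lists. For each list the number of members called over all probe sets is given, with the number called when p-values were adjusted over the list alone. The lists were collagens and matrix proteins, matrix proteases and their inhibitors, TGF-beta, BMP and Wnt pathway genes, angiogenesis and growth factors, cytokines with chemokines and their receptors, antigen presentation, complement and coagulation, interferon-induced genes, lysosome and phagocytosis, cytoskeleton and cell motility, cell cycle, fatty acid oxidation, respiratory chain, citric acid cycle and pyruvate dehydrogenase, glycolysis and glucose transport, sarcomere and cardiomyocyte markers, fetal and stress-induced cardiac genes, calcium handling and ion channels, hypoxia-induced genes, antioxidant and metallothionein genes, heat shock and endoplasmic reticulum stress, immediate early genes, apoptosis, circadian clock, glucocorticoid-responsive genes and sex-linked genes. Marker lists covered macrophages and monocytes, neutrophils, lymphocytes, fibroblasts, endothelium, smooth muscle and pericytes, red blood cells, atrium, mesothelium and epicardium, adipocytes, skeletal muscle, lung, and nerve with Schwann cells.

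Named genes followed a rule: the 10 largest increases and 10 largest decreases per IR comparison among called genes whose IR arrays all lay on 1 side of the sham arrays; the 5 largest each way for the comparisons of days; for each list up to 4 called members with the largest change and up to 2 uncalled members with the highest signal; and, where fewer than 5 genes were called, the 5 with the smallest p. The groups, the comparisons, the tests, the lists and this rule were chosen before the data were examined, as were all alternatives except leaving out 2 d IR replicate 69 and 7 d sham replicate 82 together. The alternatives were quantile normalization and median centring, no pseudocount and a pseudocount of 780, no filter and a filter at the 60th percentile (7132 probe sets), no intensity trend, array weights, fits of the 6 arrays compared alone, counts over genes, other sham arrays as control, other probe sets of a gene, and leaving out each array in turn.

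The analysis was tested on simulated data with 200 of the 10527 probe sets changed. The shares below describe these simulated data. They do not give the share of false calls on the real arrays, where leaving out single arrays moved the counts. For 2 d IR against sham, 16.4% of changes of 0.5 on the log2 scale, 76.1% of changes of 1 and 100% of changes of 2 were called, with 5.9% false among the calls. For 7 d IR against sham the shares were 20.9%, 83.6% and 97%, with 5% false. For the interaction they were 9%, 46.3% and 89.4%, with 7.7% false; for the averaged effect 46.3%, 92.5% and 100%, with 6.5% false; for the sham hearts over time 22.4%, 86.6% and 100%, with 6.1% false; and for the IR hearts over time 17.9%, 80.6% and 95.5%, with 5.1% false. Tables were prepared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots with matplotlib 3.10.9.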

Results

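Gene expression was measured in the ventricles of 12 rats with an oligonucleotide array that reads each transcript through 1 or more sets of short probes. In IR rats (ischaemia and reperfusion) the left anterior descending coronary artery, which supplies the front wall of the left ventricle, was closed for 30 min and reopened, and the ventricle was taken 2 or 7 days later. In sham rats the artery was not occluded. Each of the 4 groups (2 d sham, 2 d IR, 7 d sham and 7 d IR) held 3 rats, and all values below are from 3 against 3 arrays unless stated.

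The first principal component carried 39.0% of the variance over the 10527 probe sets tested and ran from the 2 d sham arrays, at -25.28 to -17.65, to the 7 d IR arrays, at 20.05 to 31.73. The second carried 12.8% and placed the 2 d IR arrays lowest. An array stood apart from its group in 2 groups. 2 d IR replicate 69 lay at 18.30 on the first component, against -4.11 and 0.18 for replicates 73 and 76, and 7 d sham replicate 82 lay at -23.62, against -1.06 and -1.14 for replicates 80 and 81. The mean correlation between arrays of a group was 0.960 to 0.969 and that between 2 d sham and 7 d IR arrays was 0.917.

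**Figure D1:**
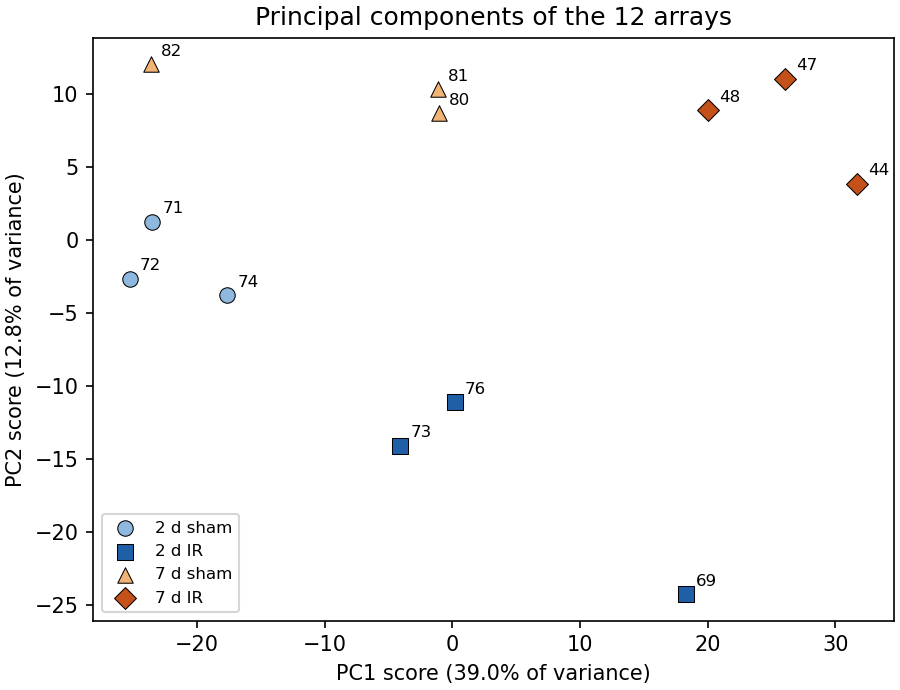
Scores of the 12 arrays on the first (39.0% of variance) and second (12.8%) principal components of log2 signal (arbitrary units); each point is 1 rat, labelled with its replicate number, with a colour and symbol per group. Replicate 69 (18.30) lies to the right of the other 2 d IR arrays and replicate 82 (-23.62) to the left of the other 7 d sham arrays.

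At 2 d, the comparison of IR with sham asked which transcripts differed early after reperfusion. Genes of macrophages, chemokines and the cytoskeleton rose. Lilrb4, an inhibitory receptor of myeloid cells, was 5.63-fold higher in IR hearts (log2 change 2.49, SE 0.33, adjusted p = 0.00794), and Cd53, a tetraspanin of white blood cells, was 3.36-fold higher (1.75, SE 0.21, adjusted p = 0.00316). Hmox1, the enzyme that degrades haem, rose 4.04-fold (2.01, SE 0.31, adjusted p = 0.0132). Tnc, a matrix glycoprotein of healing wounds, rose 3.68-fold (1.88, SE 0.34, adjusted p = 0.0176), from a mean signal of 541 ± 176 to 2478 ± 329 (SD, n = 3). Angptl4, an inhibitor of lipoprotein lipase, rose 3.51-fold (1.81, SE 0.38, adjusted p = 0.0285), and Cd300c2, a receptor gene of the CD300 family, rose 3.62-fold (1.85, SE 0.32, adjusted p = 0.0167).

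Of 25 macrophage and monocyte markers tested at 2 d, 14 rose and 0 fell (17 and 0 adjusted over the list alone; camera adjusted p = 8.4e-15, and adjusted p = 0.283 with an estimated correlation). Gpnmb, a glycoprotein of phagocytes, rose by 1.99 (SE 0.35), Lgals3, which encodes galectin-3, by 1.65 (SE 0.25), and Clec4a3, a lectin receptor, by 1.39 (SE 0.31). The mean of this list over its members was 1.34 above the sham mean on replicate 69, the array that stood apart, against 0.63 and 0.81 on the other 2 d IR arrays. Among 39 cytokines, chemokines and receptors, 5 rose (17 adjusted over the list alone; adjusted p = 0.283 with an estimated correlation). Cxcl1, which attracts neutrophils, rose by 2.11 (SE 0.51, adjusted p = 0.0448), and Ccl2, which attracts monocytes, by 1.77 (SE 0.39, adjusted p = 0.0326). Spp1, which encodes osteopontin, had a mean signal of 30397 ± 12575 in IR and 8723 ± 2595 in sham hearts (SD, n = 3) and did not pass (1.73, SE 0.53, adjusted p = 0.0856), although it did without 7 d IR replicate 48 (adjusted p = 0.0228). Among 37 lysosomal and phagocytic genes 6 rose (13 adjusted over the list alone; adjusted p = 0.283 with an estimated correlation). The cathepsins Ctsz and Ctss rose by 1.56 (SE 0.26) and 1.28 (SE 0.29).

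Genes of the cytoskeleton also rose at 2 d, with a few of the cell cycle and of the matrix. Of 47 cytoskeletal and motility genes, 15 rose (32 higher and 2 lower adjusted over the list alone; camera adjusted p = 1.76e-15, and adjusted p = 0.283 with an estimated correlation). Among them were Plek, a protein kinase C substrate of blood cells (1.79, SE 0.38), the tubulins Tubb6 (1.52, SE 0.28) and Tubb2a (1.20, SE 0.21), and Actn1, a non-muscle actinin (1.15, SE 0.25). Of 38 cell cycle genes, 3 were called and 20 were higher adjusted over the list alone. All 38 had a positive change (median 0.49; adjusted p = 0.283 with an estimated correlation). The 3 were Mcm2, part of the helicase that opens replication origins (0.94, SE 0.17), Cdca3 (0.97, SE 0.20) and the kinesin Kif22 (0.93, SE 0.22). The mean of the cell cycle list lay 0.772 above the sham mean on replicate 69, against 0.333 and 0.509 on the other 2 d IR arrays. Among 17 matrix proteases and inhibitors 3 rose (7 adjusted over the list alone; adjusted p = 0.319 with an estimated correlation). They were Mmp12, the macrophage elastase (1.88, SE 0.44), Mmp14 (1.24, SE 0.31) and Plau, the urokinase (1.05, SE 0.23); another probe set of Plau gave 0.40 and did not pass (adjusted p = 0.295). Of 46 collagens and matrix proteins, 2 rose (14 adjusted over the list alone; adjusted p = 0.32 with an estimated correlation), Tnc and the fibronectin gene Fn1 (1.39, SE 0.33).

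The genes that fell at 2 d were fewer. The largest decrease was that of Rpl37a, a protein of the large ribosomal subunit, by 1.31 (SE 0.15, adjusted p = 0.00316); its signal was 39104 to 55717 in the 2 d sham hearts and 13025 to 20756 in the other 9. Others were Rab3a, a GTPase of vesicle release, with -1.03 (SE 0.14, adjusted p = 0.0108), Dhrs7c, a dehydrogenase of muscle, with -0.83 (SE 0.20), and Slc2a4, the insulin-responsive glucose transporter, with -0.75 (SE 0.18, adjusted p = 0.0448). Few members of the lists of cardiomyocyte metabolism were called over all probe sets, and many more adjusted over the list alone. The counts were 2 against 46 of 73 respiratory chain genes and 2 against 18 of 28 genes of the citric acid cycle and pyruvate dehydrogenase, all lower. They were 2 against 14 of 39 fatty acid oxidation genes, 2 against 20 of 31 sarcomere and cardiomyocyte markers, and 2 against 6 of 29 glycolysis and glucose transport genes, all lower. The list p-values with an estimated correlation were adjusted p = 0.283 for these lists, except fatty acid oxidation with adjusted p = 0.32. Examples were Ndufs1 of complex I (-0.54, SE 0.11), Mpc1 of the mitochondrial pyruvate carrier (-0.65, SE 0.16), Acsl1, which activates fatty acids (-0.66, SE 0.17), and Tnni3, cardiac troponin I (-0.47, SE 0.11). Other probe sets of Acsl1 and Slc2a4 gave -0.53 and -0.64 and did not pass (adjusted p = 0.11 and 0.0512). On replicate 69 the sarcomere list lay 0.57 below the sham mean (-0.57), against -0.18 and -0.28 on the other 2 d IR arrays. The fatty acid oxidation list lay at -0.579 on replicate 69, against -0.108 and -0.235 on the other 2 d IR arrays. Nppa, the atrial natriuretic peptide, did not pass (-0.74, SE 0.25, adjusted p = 0.112).

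In all, limma called 260 of 10527 probe sets at 2 d, 198 higher and 62 lower in IR hearts (76.2% higher), which is 202 genes; 63 genes were at least 2-fold higher and 4 at least 2-fold lower. After median centring of the arrays 277 were called, 173 higher and 104 lower (62.5% higher). The IR arrays all lay above or all below the sham arrays for 2780 probe sets, or 26.4%, where chance gives 10%. The count rests on single arrays. It was 2 without 2 d IR replicate 69, 2 without 2 d sham replicate 71, 2 without 2 d sham replicate 72, 100 without 2 d sham replicate 74 and 147 without 2 d IR replicate 76. It was 515 without 2 d IR replicate 73 and 501 without 7 d sham replicate 82. Cd53 and Rpl37a were the 2 of 53 named genes that passed in all 12 fits with an array left out, and the other named genes of this comparison lost their call in at least 1 of them. Without replicates 69 and 82 together the count was 70, without a filter on dim probe sets 77, and without the intensity trend 68. Of 7 values from other probe sets of 6 of the named genes, 2 passed and 5 did not.

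At 7 d, the same question was put to the later hearts, and genes of the extracellular matrix were among the largest increases. Col5a3, a fibrillar collagen, was 5.58-fold higher in IR hearts (log2 change 2.48, SE 0.36, adjusted p = 0.00323), at a mean signal of 1427 ± 467 against 89.6 ± 50.3 in sham hearts (SD, n = 3). The sham level lies under the pseudocount of 195, so that this fold understates the ratio of the signals. Loxl1, which crosslinks elastin, rose 3.85-fold (1.94, SE 0.21, adjusted p = 0.00092). The secreted Wnt modulators Sfrp2 and Sfrp4 rose 3.96-fold (1.99, SE 0.29, adjusted p = 0.00323) and 4.8-fold (2.26, SE 0.42, adjusted p = 0.00816), and Tnn, the matrix protein tenascin-N, rose 4.61-fold (2.20, SE 0.53, adjusted p = 0.0178). Another probe set of Sfrp4 gave -0.32 and did not pass. Of 3 measures of RNA integrity, 1 separated the groups of this day: the log2 ratio of the 3' over the 5' probe set of Actb was 0.18 ± 0.06 in 7 d IR and 0.58 ± 0.23 in 7 d sham hearts (SD, n = 3; exact permutation p = 0.1, the smallest possible). That of Gapdh was 0.32 ± 0.05 and 0.39 ± 0.07 (exact permutation p = 0.2) and that of hexokinase 0.82 ± 0.16 and 0.95 ± 0.24 (exact permutation p = 0.6). At 2 d the Actb ratio was 0.24 ± 0.07 and 0.20 ± 0.10 (exact permutation p = 0.8).

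Of 46 collagens and matrix proteins, 27 rose at 7 d and 0 fell (34 and 0 adjusted over the list alone; median 0.79; camera adjusted p = 2.29e-19, and adjusted p = 0.207 with an estimated correlation). Of 34 fibroblast and myofibroblast markers, 17 of them also in another list, 23 rose (28 adjusted over the list alone; median 0.98; adjusted p = 0.207 with an estimated correlation). They included Ltbp2, a latent TGF-beta binding protein (1.80, SE 0.44), the secreted Ccn5 (1.71, SE 0.26) and the crosslinking enzyme Lox (1.60, SE 0.33; 1.02 and not past the threshold on another probe set). Among 17 matrix proteases and inhibitors 8 rose (9 adjusted over the list alone; adjusted p = 0.207 with an estimated correlation). Ctsk, cathepsin K, had 1.42 (SE 0.25), Mmp14 1.39 (SE 0.31) and Mmp2 1.24 (SE 0.22); another probe set of Mmp2 gave -0.09 and did not pass. Of 42 TGF-beta, BMP and Wnt pathway genes, 10 rose and 0 fell (14 and 0 adjusted over the list alone; adjusted p = 0.207 with an estimated correlation), among them Fstl1, a secreted follistatin-like protein (1.35, SE 0.22). At 2 d, 0 rose and 1 fell in that list, the BMP receptor Bmpr1a (-0.80, SE 0.16; 1 higher and 1 lower adjusted over the list alone; adjusted p = 0.392 with an estimated correlation). The sham array that stood apart moved with these lists. The fibroblast list lay at -0.44 from the sham mean of the day on replicate 82 and at 0.32 and 0.12 on replicates 80 and 81, against 0.88 to 0.98 on the 7 d IR arrays.

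White blood cell genes were higher in the 7 d IR hearts too. Of 25 macrophage and monocyte markers, 14 rose (18 adjusted over the list alone; median 0.85; adjusted p = 0.207 with an estimated correlation). They included Gpnmb (1.66, SE 0.35), Clec4a3 (1.58, SE 0.31) and Cd14, the endotoxin co-receptor (1.14, SE 0.26). With the 2 d sham hearts as control Gpnmb had 0.87 and did not pass (adjusted p = 0.0853). Lgals3 did not pass at 7 d (0.65, SE 0.25, adjusted p = 0.102); it had 0.29 without 7 d sham replicate 82, and 0.82 with the 2 d sham hearts as control, where it passed (adjusted p = 0.0263). Spp1 did not pass either (0.84, SE 0.53, adjusted p = 0.329). Spp1 changed sign without 7 d IR replicate 48, at -0.002, and with sham hearts of the other day as control. Of 37 lysosomal and phagocytic genes, 15 rose (19 adjusted over the list alone; adjusted p = 0.207 with an estimated correlation), including Anxa1, an annexin that dampens inflammation (1.18, SE 0.19). Among 20 complement and coagulation genes 4 rose (5 adjusted over the list alone; adjusted p = 0.372 with an estimated correlation). They were C1qa (1.02, SE 0.22), C1qb (0.87, SE 0.26) and C1qc (0.88, SE 0.25), the subunits of C1q, and Cfd, complement factor D (0.94, SE 0.21). Of 39 cytokines, chemokines and receptors, 3 rose (3 adjusted over the list alone; adjusted p = 0.465 with an estimated correlation), led by the chemokine Ccl6 (1.56, SE 0.27). Of 47 cytoskeletal and motility genes, 15 rose (26 adjusted over the list alone; adjusted p = 0.207 with an estimated correlation). Of 38 cell cycle genes, 2 rose (1 adjusted over the list alone; adjusted p = 0.602 with an estimated correlation). The macrophage list lay at -0.42 from the sham mean of the day on replicate 82 and at 0.22 and 0.20 on replicates 80 and 81, against 0.62 to 0.93 on the 7 d IR arrays.

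Transcripts of mitochondrial energy supply and of the contractile apparatus fell at 7 d. Of 73 respiratory chain genes, 53 fell and 0 rose (68 and 0 adjusted over the list alone; median -0.46; camera adjusted p = 2.85e-27, and adjusted p = 0.207 with an estimated correlation). Examples were Cox5a (-0.83, SE 0.14) and Cox7a1 (-0.91, SE 0.20) of cytochrome c oxidase and Ndufs8 of complex I (-0.77, SE 0.13). Of 39 fatty acid oxidation genes, 27 fell (33 adjusted over the list alone; median -0.61; adjusted p = 0.207 with an estimated correlation). Eci1, an isomerase of the oxidation of unsaturated fatty acids, had -1.10 (SE 0.18, adjusted p = 0.00548) and a mean signal of 8612 ± 1402 in IR and 18810 ± 4346 in sham hearts (SD, n = 3). Of 28 genes of the citric acid cycle and pyruvate dehydrogenase, 20 fell (25 adjusted over the list alone; adjusted p = 0.207 with an estimated correlation). The cycle enzyme genes Ogdh and Suclg1 had -0.73 (SE 0.15) and -0.65 (SE 0.12). Of 31 sarcomere and cardiomyocyte markers, 19 fell (30 adjusted over the list alone; median -0.46; adjusted p = 0.207 with an estimated correlation). The alpha myosin heavy chain gene Myh6 had -0.79 (SE 0.17, adjusted p = 0.0131) and Actn2, the actinin of the Z-disc, -0.75 (SE 0.12). Of 34 calcium handling and ion channel genes, 10 fell (13 adjusted over the list alone; adjusted p = 0.207 with an estimated correlation). Examples were Hrc, a calcium-binding protein of the sarcoplasmic reticulum (-0.72, SE 0.16), and the potassium channel Kcnk3 (-0.94, SE 0.18). Other probe sets of Kcnk3 gave -0.24 and -0.35 and did not pass (adjusted p = 0.49 and 0.198). At 2 d 1 of them fell, the adrenergic receptor Adra1b (-0.64, SE 0.14; 8 adjusted over the list alone; adjusted p = 0.283 with an estimated correlation). Of 29 glycolysis and glucose transport genes, 9 fell (1 higher and 13 lower adjusted over the list alone; adjusted p = 0.207 with an estimated correlation). The muscle enzymes Pgam2 and Eno3 had -0.97 (SE 0.19) and -0.75 (SE 0.23), the latter not past the threshold with the 2 d sham hearts as control (-0.62, adjusted p = 0.0584). On the sham arrays the respiratory chain list lay at 0.17 from their mean on replicate 82 and at -0.14 and -0.03 on replicates 80 and 81, against -0.55 to -0.42 on the 7 d IR arrays.

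Among the largest single decreases at 7 d were Macrod1, a mitochondrial ADP-ribose hydrolase (-1.13, SE 0.17), Mypn, the sarcomere protein myopalladin (-1.09, SE 0.18), and Tuba8, an alpha tubulin (-1.26, SE 0.29). C10h16orf89 had -1.06 (SE 0.19), and 0.10 with the 2 d sham hearts as control. Of 18 fetal and stress-induced cardiac genes, 2 rose and 1 fell (4 and 4 adjusted over the list alone; adjusted p = 0.944 with an estimated correlation). They were the smooth muscle actin Acta2 (0.91, SE 0.24), Csrp1 (0.64, SE 0.19) and the beta myosin heavy chain Myh7 (-0.39, SE 0.11; -0.48 and not past the threshold on another probe set). At 2 d, 0 of the 18 were called (0 adjusted over the list alone; adjusted p = 0.926 with an estimated correlation, median 0.02 with a test in the negative direction). Nppa did not pass (-0.34, SE 0.25, adjusted p = 0.417). Its value was -0.22 without 7 d IR replicate 44, -0.14 without replicate 47, -0.64 without replicate 48, and 0.12 with the 2 d sham hearts as control.

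Markers of other cells of the heart were followed on both days. Of 28 endothelial markers, 0 were called at 2 d (0 adjusted over the list alone; adjusted p = 0.576 with an estimated correlation). At 7 d, 4 rose (4 adjusted over the list alone; adjusted p = 0.396 with an estimated correlation), such as the adhesion molecule Vcam1 (0.83, SE 0.23) and Cd93 (1.00, SE 0.28). Of 20 smooth muscle and pericyte markers, 0 were called at 2 d (0 adjusted over the list alone; adjusted p = 0.907 with an estimated correlation). Of these, 6 rose at 7 d (10 adjusted over the list alone; adjusted p = 0.355 with an estimated correlation), including Mcam (0.91, SE 0.18; 0.53 and not past the threshold on another probe set) and the pericyte gene Rgs5 (0.76, SE 0.16). Of 34 fibroblast markers 3 had risen at 2 d (10 adjusted over the list alone; adjusted p = 0.392 with an estimated correlation). These were S100a4 (0.99, SE 0.24), S100a11 (0.93, SE 0.20) and the cadherin Cdh11 (0.84, SE 0.16). Of 9 atrial markers, 0 were called at 2 d (0 adjusted over the list alone; adjusted p = 0.375 with an estimated correlation). At 7 d, 4 fell (1 higher and 5 lower adjusted over the list alone; adjusted p = 0.335 with an estimated correlation), and the atrial myosin light chain Myl7 had -1.75 (SE 0.50, adjusted p = 0.0366). With the 2 d sham hearts as control Myl7 had -0.04 (adjusted p = 0.965), and its signal ran from 2756 to 9699 among the 7 d sham hearts. Of 3 neutrophil markers, 0 were called at 2 d (2 adjusted over the list alone; adjusted p = 0.392 with an estimated correlation), where the calgranulin S100a9 had 1.31 (SE 0.34, adjusted p = 0.056). It passed at that value without 7 d IR replicate 44 (adjusted p = 0.0479), 7 d sham replicate 81 (0.0427) or 7 d sham replicate 82 (0.0207). At 7 d 1 rose, S100a8, its partner (1.51, SE 0.43; 1 adjusted over the list alone; adjusted p = 0.465 with an estimated correlation). Of 9 lymphocyte markers, 0 were called at 2 d (0 adjusted over the list alone; adjusted p = 0.417 with an estimated correlation). At 7 d 2 of these 9 rose, Cd4 (0.75, SE 0.19) and Cd48 (0.68, SE 0.16), with 3 adjusted over the list alone (adjusted p = 0.246 with an estimated correlation). These 2 genes do not show that lymphocytes rose.

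**Figure D2:**
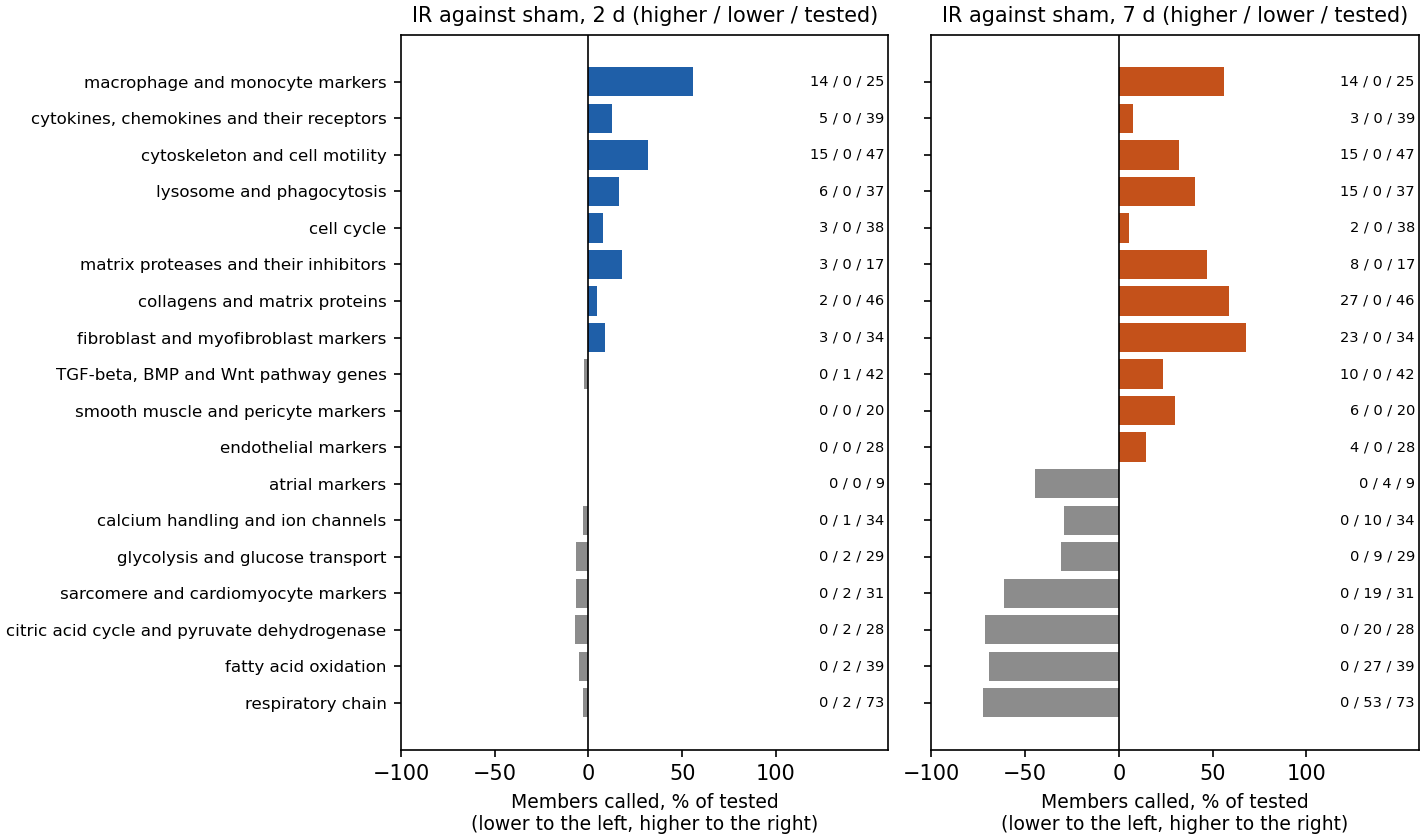
Share of the tested members of 18 gene lists called in IR against sham at 2 d (left) and 7 d (right), in percent. Coloured bars are members higher in IR, grey bars members lower, and the numbers give higher, lower and tested members. At 7 d, 23 of 34 fibroblast markers were higher.

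**Figure D3:**
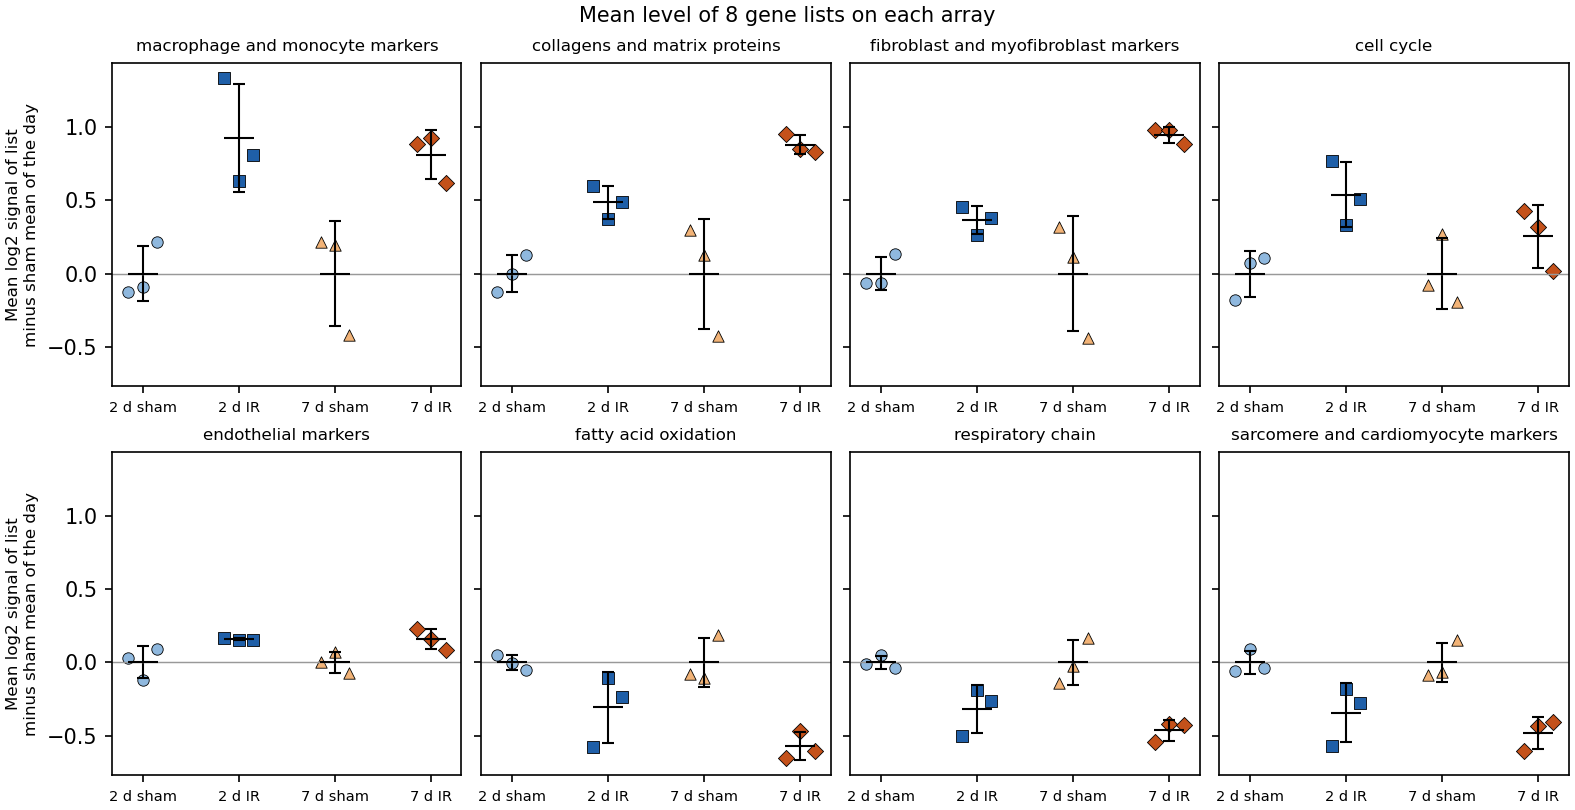
Mean log2 signal of the members of 8 gene lists on each array, minus the mean of the sham arrays of the same day; points are rats (n = 3 per group), horizontal lines group means and error bars SD. The 7 d sham arrays span -0.44 to 0.32 on the fibroblast list, and 2 d IR replicate 69 is at 1.34 on the macrophage list.

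In all, 1270 probe sets were called at 7 d, 655 higher and 615 lower in IR hearts (51.6% higher), which is 1001 genes; 111 genes were at least 2-fold higher and 14 at least 2-fold lower. After median centring 1251 were called, 474 higher and 777 lower (37.9% higher). For 3410 probe sets, or 32.4%, the IR and sham arrays did not overlap, where chance gives 10%. The count was 175 without 7 d sham replicate 82, 474 without 7 d IR replicate 44, 502 without 7 d IR replicate 47 and 541 without replicates 69 and 82 together. With all 6 sham arrays as control 2428 were called, and with the 2 d sham arrays 2505. With the 2 d sham arrays, 11 of the 110 named genes that had passed kept their sign and lost their call, among them Gpnmb, Eno3 and Myl7, and C10h16orf89 changed sign. Others were larger with that control, such as Mmp14 (3.04), C1qa (2.03) and Vcam1 (1.73). The replicate numbers of the 7 d IR rats lie apart from those of the other 9; if they mark a batch, it cannot be told apart from the 7 d IR group here, in the interaction, in the average over both days or in IR hearts over time. Of 110 named genes that passed, 28 passed in all 12 fits with an array left out, among them Col5a3, Loxl1, Sfrp2, Tnc, Eci1, Cox5a and Actn2; the others lost their call in at least 1. Of 27 values from other probe sets of 21 named genes, 9 passed in the same direction, 14 had the same sign and did not pass, and 4 had the opposite sign.

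**Figure D4:**
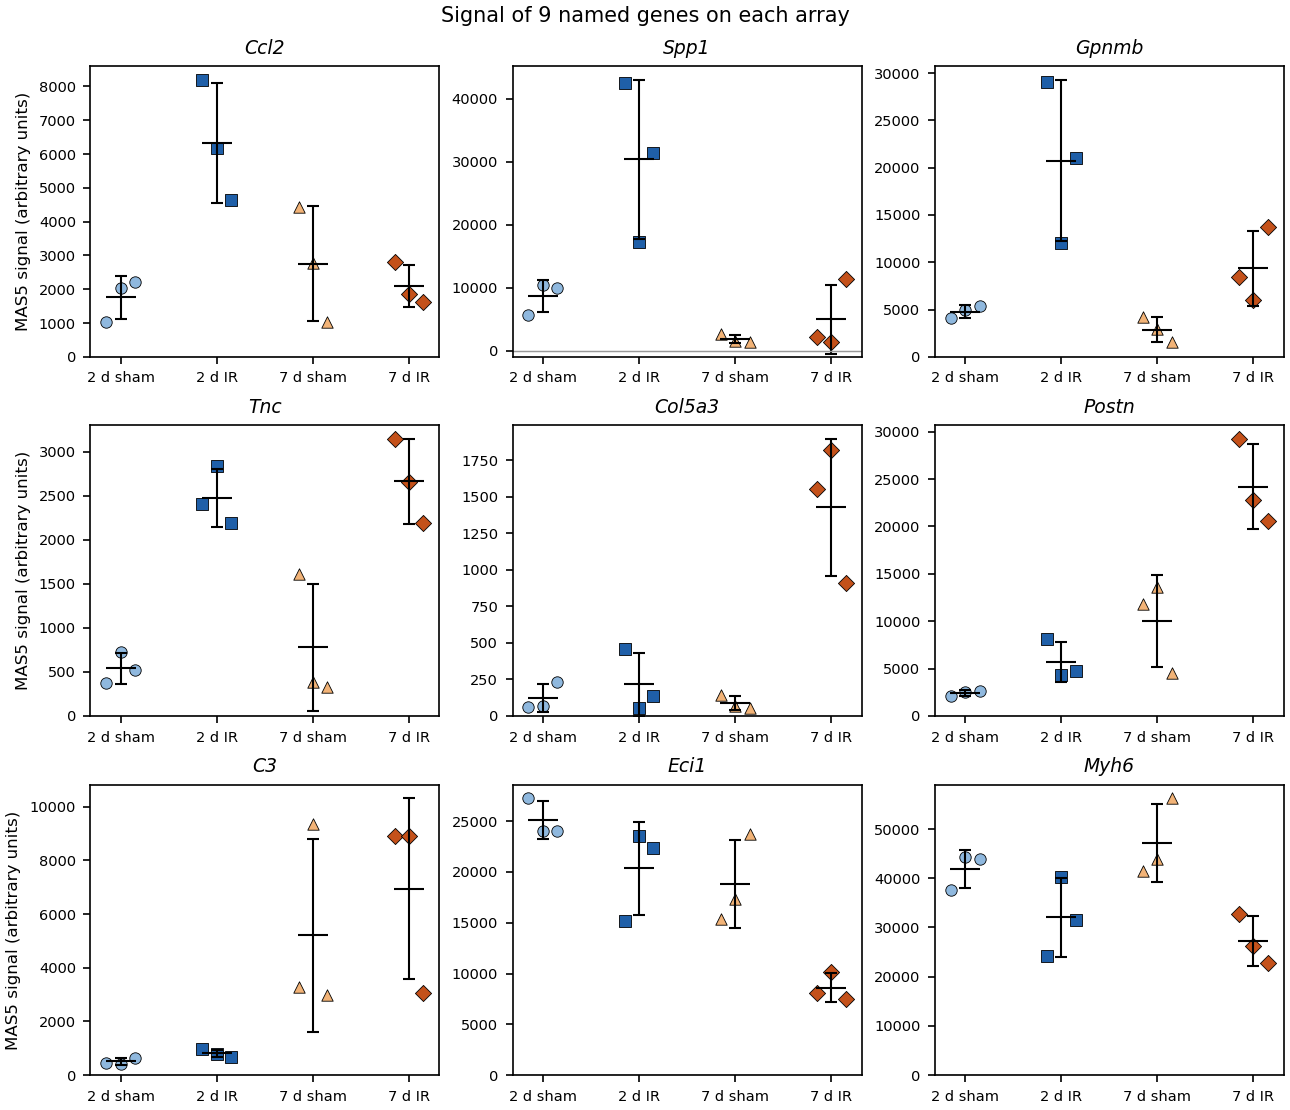
MAS5 signal (arbitrary units, linear axes from 0 or, where the error bar reaches below, from just under 0) of 9 named genes; points are rats (n = 3 per group), horizontal lines group means and error bars SD. Col5a3 has a mean of 1427 in 7 d IR hearts and 89.6 in 7 d sham hearts, and C3 is near 514 to 809 at 2 d and 5211 to 6954 at 7 d in both sham and IR hearts.

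The effects of IR on both days went mostly the same way. Of the probe sets called at 2 d, 251 of 260 (96.5%) had the same sign at 7 d, and of those called at 7 d, 1171 of 1270 (92.2%) had the same sign at 2 d. Both days called 88 probe sets higher, against 12.3 for independent lists (odds ratio 13.8, Fisher's exact p = 3.49e-54), and 29 lower, against 3.6 (odds ratio 14.8, Fisher's exact p = 5.94e-20); 0 were called in opposite directions. The log2 changes of the days correlated across probe sets, which are not independent replicates, at Pearson's r = 0.581 and Spearman's rho = 0.568. The days have separate sham groups, so the overlap holds no shared control. Both comparisons do share the estimate of spread of each probe set, so that their calls are not independent. The expected counts of 12.3 and 3.6 and Fisher's exact test make no allowance for that. The overlap of 117 probe sets was 29 without replicates 69 and 82 together, 33 without a filter, 29 without the intensity trend and 182 with the stricter filter, and with single arrays left out it ran from 1 to 234.

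**Figure D5:**
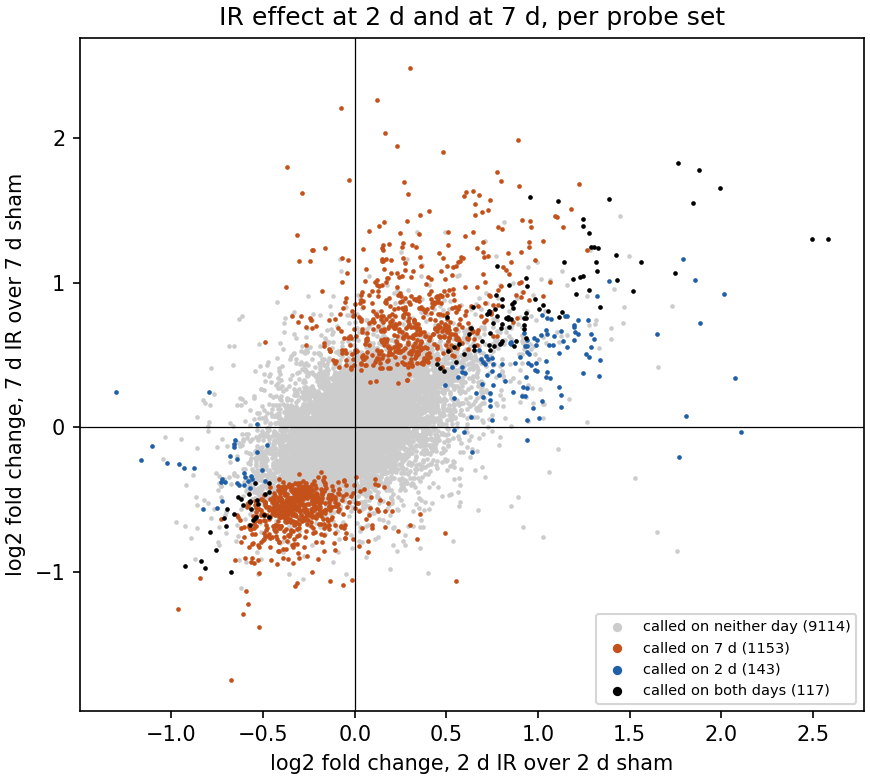
Log2 fold change of IR over sham at 2 d (horizontal axis) and 7 d (vertical axis) for the 10527 probe sets tested; each point is a probe set, coloured by the day or days on which it was called. Both days called 117, 2 d alone 143 and 7 d alone 1153, mostly at the lower left or upper right.

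Calls on a single day do not show that the days differ, and the difference of the IR effects was tested itself. Rpl37a was called, with an effect 1.55 higher at 7 d than at 2 d (SE 0.21, adjusted p = 0.0287), with its high signal in the 2 d sham hearts. It was the only call, and 752 probe sets had an unadjusted p under 0.05, where chance gives 526. It lost its call in 9 of the 12 fits with an array left out. The genes with the next smallest p did not pass. They were Loxl1 with 1.71 (SE 0.30, adjusted p = 0.151), and C10h16orf89 with -1.61 (SE 0.27, adjusted p = 0.151). Loxl1 passed without 7 d sham replicate 80 (1.92, adjusted p = 0.026) and C10h16orf89 without 2 d sham replicate 71 (-1.82, adjusted p = 0.0292). Sparc, a collagen-binding matrix protein, had 1.11 (SE 0.22, adjusted p = 0.224), and Plin2, a lipid droplet protein, had -0.95 (SE 0.19, adjusted p = 0.224).

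Averaged over both days, with 6 IR and 6 sham arrays, 2414 probe sets were called, 1307 higher and 1107 lower (54.1% higher), in 1867 genes; after median centring 2463 were called, 975 higher and 1488 lower (39.6% higher). Of the lists of heart muscle, 65 of 73 respiratory chain genes, 25 of 28 genes of the citric acid cycle and pyruvate dehydrogenase, 29 of 31 sarcomere markers and 30 of 39 fatty acid oxidation genes were lower. Of the lists of stroma and white blood cells, 35 of 46 collagens and matrix proteins, 21 of 25 macrophage markers and 21 of 34 fibroblast markers were higher. Of 38 cell cycle genes 15 were higher, and of 47 cytoskeletal genes 32 were higher and 1 lower. With an estimated correlation the adjusted p of each list was 0.2 or more. The count was 1569 without 2 d IR replicate 69 and 1039 without replicates 69 and 82 together.

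Between 2 d and 7 d after sham surgery few transcripts were called. In limma 992 probe sets had an unadjusted p under 0.05, where chance gives 526, so that the few calls do not show an absence of change. C3, the central complement component, was 6.74-fold higher at 7 d (log2 change 2.75, SE 0.40, adjusted p = 0.0216), at a mean signal of 5211 ± 3593 against 514 ± 123 (SD, n = 3). S100a9 rose 4.37-fold (2.13, SE 0.34, adjusted p = 0.033), Dmbt1, a secreted scavenger receptor of epithelia, 2.52-fold (1.33, SE 0.21, adjusted p = 0.033), and C10h16orf89 2.23-fold (1.16, SE 0.19, adjusted p = 0.0368). Rpl37a fell by 1.75, and Ptgds, a prostaglandin D2 synthase, fell by 1.34. Spp1 had -2.10 (SE 0.53, adjusted p = 0.196) and Serping1, the inhibitor of complement C1, 1.01 (SE 0.20, adjusted p = 0.092); neither passed. Serping1 passed without 7 d sham replicate 82 (1.20, adjusted p = 0.00978) and Spp1 without 7 d IR replicate 48 (-2.10, adjusted p = 0.0273). Of 20 complement and coagulation genes 1 rose (8 adjusted over the list alone; camera adjusted p = 2.84e-08, and adjusted p = 0.384 with an estimated correlation). Of 46 collagens and matrix proteins, 0 were called (12 higher and 2 lower adjusted over the list alone; camera adjusted p = 1.25e-10, and adjusted p = 0.385 with an estimated correlation). In all 8 probe sets were called, 6 higher and 2 lower. The count was 76 without 7 d sham replicate 82 and 83 without replicates 69 and 82 together. It was 1 without 2 d sham replicate 72, 1 without 7 d sham replicate 81, 2 without 2 d sham replicate 71, and 3 without 2 d IR replicate 73. It was 3 without 7 d sham replicate 80, 4 without 7 d IR replicate 47 and 5 without 2 d sham replicate 74.

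From 2 d to 7 d of reperfusion, matrix genes rose and the chemokine Ccl2 and Spp1 fell. This comparison holds time after surgery as well as any change of the IR effect. Tnn rose 7.87-fold (2.98, SE 0.53, adjusted p = 0.00523), Sfrp2 5.24-fold (2.39, SE 0.29, adjusted p = 0.000686) and Postn, the matrix protein periostin, 4.23-fold (2.08, SE 0.32, adjusted p = 0.00232). The type I collagen gene Col1a1 rose by 1.88 (SE 0.33) and the growth factor Igf1 by 1.58 (SE 0.25). The plasma protein genes C3 and Lbp, the lipopolysaccharide-binding protein, rose 6.47-fold (2.69, SE 0.40) and 6.73-fold (2.75, SE 0.43), and C3 had risen as well between the sham groups. Between the sham groups Postn had 1.83 (SE 0.32, adjusted p = 0.0527), Col1a1 1.58 (SE 0.33, adjusted p = 0.112) and Lbp 1.89 (SE 0.43, adjusted p = 0.137). They did not pass, but without 7 d sham replicate 82 each did, at 2.32, 2.11 and 2.33. Spp1 fell by 3.00 (SE 0.53, adjusted p = 0.0054), Ccl2 by 1.51 (SE 0.39, adjusted p = 0.0447), Hmox1 by 1.31 (SE 0.31) and Hamp, the iron hormone hepcidin, by 1.89 (SE 0.35). The mean signal of Spp1 was lower in 7 d than in 2 d sham hearts too (1884 ± 667 against 8723 ± 2595, SD, n = 3), though it did not pass there. That of Ccl2 was not lower (2753 ± 1696 against 1758 ± 643). Of 46 collagens and matrix proteins, 23 rose and 1 fell, Spp1 (32 and 1 adjusted over the list alone), and of 34 fibroblast markers 19 rose (23 adjusted over the list alone). Of 20 complement and coagulation genes 9 rose (10 higher and 2 lower adjusted over the list alone). Of 39 fatty acid oxidation genes, 9 fell (23 adjusted over the list alone), among them Eci1 (-1.21, SE 0.18) and Acot2 (-1.38, SE 0.33). With an estimated correlation the adjusted p of each list was 0.192 or more. In all 363 probe sets were called, 258 higher and 105 lower. The count was 192 without 2 d IR replicate 73, 213 without 2 d IR replicate 76, 211 without 7 d IR replicate 47, 231 without 7 d IR replicate 44 and 241 without 7 d IR replicate 48. It was 577 with array weights and 556 without replicates 69 and 82 together.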

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

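The tests of the share of cardiomyocytes, of the fall in cardiomyocyte transcripts, of a deviating array for Rpl37a and of wrong labels for replicates 69, 80 and 81 were chosen only after the results were seen. The splits of the arrays and the scaling test were planned. The prediction of the ribosomal test was written before that test was run, but for a gene that the results had singled out.

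In IR hearts the called cardiomyocyte genes were lower and the called stromal and white blood cell genes higher, mostly at 7 d and in the average over both days; at 2 d 2 of 31 sarcomere, 3 of 34 fibroblast and 14 of 25 macrophage markers were called, and 0 lists passed with an estimated correlation on either day. The values argue against a lower share of cardiomyocytes as the only change, most clearly at 7 d. That alone would raise the markers of all other cells by a like factor. Over both days the fibroblast list rose by 0.66 and the endothelial list by 0.16. The difference was 0.497 (exact permutation p = 0.005, the smallest that 400 assignments can give). Dim genes rise less on the scale used, and the brightness of the lists was not compared. A positive change was seen in 33 of 34 fibroblast and 17 of 28 endothelial markers. The sign of a small change in a dim gene is also less certain, so these counts do not remove that limit. At 7 d the mean changes were 0.948 and 0.16. At 2 d they were 0.365 and 0.158, a smaller gap that was not tested alone. However, 17 of 34 fibroblast and 8 of 28 endothelial markers stand in another list. Single bright markers also vary at 7 d. For endothelium Cav1 had 0.24 on 1 probe set and 1.16 on another. Fabp4 had -0.27, with -0.10 without 7 d sham replicate 82 and -0.43 without replicate 80. For fibroblasts Dcn had 0.17, and 0.11 without 7 d IR replicate 47. The authors' global scaling moves all probe sets of an array the same way, so it could not alone give both directions. The scaling test by quantile normalization could therefore hardly come out otherwise and decides nothing further. After quantile normalization the fatty acid oxidation list kept a median of -0.549 at 7 d and the collagen list 0.84. The level of the arrays does bear on the balance of calls. At 7 d 51.6% of calls were higher, and 37.9% after median centring. A like fall in cardiomyocyte transcripts may account for the lower part of the pattern. Over both days the fatty acid oxidation list (-0.44) and the sarcomere list (-0.41) differed by -0.028 (exact permutation p = 0.57). This does not show that all cardiomyocyte transcripts fell alike, as it covers 2 lists and averages over days with unlike values. The median 7 d effect minus 2 d effect was -0.262 for the fatty acid oxidation list and -0.137 for the sarcomere list. Open is whether fewer cardiomyocytes, joined by more or more active fibroblasts and macrophages, or lower expression per cell gave the pattern. IR itself is the biological difference of the design, and arrays of whole ventricle do not part these causes. At 7 d 2 technical causes stay untested as well. They are a batch, if the replicate numbers mark one, and RNA integrity, since the log2 Actb ratio was 0.18 in IR and 0.58 in sham hearts.

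Rpl37a was the only gene called for a difference of the IR effect between the days, by 1.549, and its signal was high in the 2 d sham hearts (39104, 52874 and 55717 against 13025 to 20756 elsewhere). A change of ribosomal protein transcripts as a class is argued against by the other 41 genes, which had a median of -0.063 from 2 d to 7 d sham (-0.35 to 0.31, 0 called). A single deviating array is argued against as well, since leaving out any of the 2 d sham arrays left a change of -1.655 or larger in size. The gene has 1 probe set, and a fault of that probe set common to 3 arrays, a shared property of these rats and a true difference between the sham groups may each account for it and stay untested.

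2 d IR replicate 69 and 7 d sham replicate 82 stood apart from the other arrays of their groups. A 7 d IR heart under the label of replicate 69 is argued against, as that array lay 0.205 of the way from 2 d IR to 7 d IR, near the other 2 d IR arrays at 0.023 and 0.102. IR hearts like those of either IR group under the labels of replicates 80 and 81 are argued against as well, since on that axis they lay at 0.416 and 0.484, apart from the 2 d IR arrays and from the 7 d IR arrays (0.753 to 0.982) by more than the SD of either group (0.091 and 0.118), and the fibroblast list lay at 0.32 and 0.12 on them, against 0.88 to 0.98 on the 7 d IR arrays. The axis from 2 d IR to 7 d IR follows time in IR hearts and does not part sham from IR, since replicate 82 lay on it at 0.05. From 2 d sham to 2 d IR, replicates 80 and 81 lay at 0.539 and 0.523 and replicate 82 at -0.04. The 7 d IR arrays lay there at 0.827 to 1.139. Open and untested are a response to the sham operation in replicates 80 and 81, a mild injury there, and a larger injury in replicate 69.

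By camera with the preset correlation, 13 lists also differed in their IR effect between the days. The median over the members of the 7 d effect minus the 2 d effect was 0.336 for collagens and matrix proteins, 0.431 for fibroblast markers, 0.198 for smooth muscle and pericyte markers, 0.134 for TGF-beta, BMP and Wnt pathway genes and 0.139 for angiogenesis and growth factors. It was -0.327 for cytokines and their receptors, -0.249 for cell cycle, -0.262 for fatty acid oxidation, -0.143 for the respiratory chain, -0.187 for the citric acid cycle and pyruvate dehydrogenase, -0.137 for sarcomere markers, -0.201 for heat shock and endoplasmic reticulum stress and -0.309 for glucocorticoid-responsive genes. With an estimated correlation the adjusted p of each of them was 0.731 or higher.

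Other splits of the same arrays were fitted in the same way. For the average over both days, 1 of 100 splits, the real one, called as many as 2414 probe sets, and the highest other called 544. That share is the smallest that 100 splits can give, and it makes a chance result unlikely there. For the interaction, 14 of 100 called at least 1 probe set, and chance is not excluded. Another split called 446 probe sets. That split exchanges the days of the IR hearts alone, and so tests the change from 2 d to 7 d averaged over IR and sham hearts in place of the interaction. Comparisons of 3 against 3 have 10 splits, too few for a share under 0.05. The real value and the highest other were 260 and 0 at 2 d, 1270 and 3 at 7 d, 8 and 2 in sham hearts over time, and 363 and 1 in IR hearts over time, each reached by 1 of 10 splits. For the number of passing lists they were 22 and 21 at 2 d (1 of 10) and 22 and 23 at 7 d (3 of 10); the other splits passed 1 to 21 lists at 2 d and 2 to 23 at 7 d.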

How the results depend on the processing

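The alternative without 2 d IR replicate 69 and 7 d sham replicate 82 was chosen only after the data were seen; all others were planned, and where a value changed the cause was not tested, except that fewer arrays leave fewer degrees of freedom. No paired analysis was possible because the groups share no replicate numbers.

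Without a filter on dim probe sets the counts of calls were 77 at 2 d, 0 for the interaction, 1 for sham hearts over time and 33 for the overlap of both days; with the stricter filter they were 5 for sham hearts over time and 182 for the overlap. Without the intensity trend they were 68 at 2 d, 0 for the interaction, 2 for sham hearts over time and 29 for the overlap. A pseudocount of 780 gave 2 for the interaction and 4 for sham hearts over time, and array weights gave 3, 25 for sham hearts over time and 577 for IR hearts over time. With all 6 sham arrays as control 2428 were called at 7 d, and with the 2 d sham arrays 2505. Without replicates 69 and 82 the counts were 70 at 2 d, 541 at 7 d, 0 for the interaction, 1039 for the average, 83 for sham hearts over time, 556 for IR hearts over time and 29 for the overlap. Of the 22 lists that passed on each day, 0 passed camera with an estimated correlation on either day (4 of all 39 lists at 2 d and 6 at 7 d had an unadjusted p under 0.05). Of all 39 lists, fry in its directional form passed 13 at 2 d and 15 at 7 d.

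With each array left out in turn, the counts ran from 2 to 515 at 2 d, 175 to 1463 at 7 d, 0 to 6 for the interaction and 1569 to 2439 for the average. They ran from 1 to 76 for sham hearts over time, 192 to 439 for IR hearts over time and 1 to 234 for the overlap, and passing lists from 17 to 23 at 2 d and 16 to 24 at 7 d. In these fits the named genes kept their call in 367 of 636 cases at 2 d, 1040 of 1320 at 7 d, 43 of 72 for sham hearts over time and 594 of 708 for IR hearts over time, and no called gene changed sign.

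Under the other alternatives named genes kept their call in 459 of 580 cases at 2 d, 1193 of 1313 at 7 d, 40 of 59 for sham hearts over time and 540 of 585 for IR hearts over time. Signs changed as follows. Spp1 at 7 d had -0.21 with all 6 sham arrays, -1.26 with the 2 d sham arrays as control and -0.002 without 7 d IR replicate 48, and up to 1.40 without replicate 47. C10h16orf89 at 7 d had 0.10 and Nppa 0.12 with the 2 d sham arrays as control. Other probe sets gave -0.087 for Mmp2, -0.32 for Sfrp4, -0.27 for P4ha2, which had 0.71, and 0.034 for Pdk2, which had -0.61, at 7 d, and -0.27 for Mmp2 and -0.018 for Sfrp4 in IR hearts over time. Of the values from other probe sets of named genes, 2 of 7 kept the call at 2 d, 9 of 27 at 7 d and 6 of 12 in IR hearts over time. Lists that did not pass were not followed under the alternatives. Dim signals limit the folds: a gene under the pseudocount in 1 group has its change understated.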

Other observations

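All values here were taken after the main results were seen, except the counts of the planned lists; no explanation is offered for them.

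Several smaller groups of genes had not yet been described. Of 30 antioxidant and metallothionein genes, 1 rose at 2 d, Hmox1 (1 adjusted over the list alone; median 0.03 and mean 0.07, with a test in the negative direction). At 7 d 3 rose and 3 fell (4 and 3 adjusted over the list alone). The peroxidases Prdx4 (0.88, SE 0.19) and Gpx7 (0.80, SE 0.16) rose, while Sod1, the cytosolic superoxide dismutase, fell by 0.58 (SE 0.13). Of 31 heat shock and endoplasmic reticulum stress genes, 0 were called at 2 d (13 higher and 1 lower adjusted over the list alone; adjusted p = 0.283 with an estimated correlation). At 7 d 1 rose and 3 fell (2 and 3 adjusted over the list alone; adjusted p = 0.972 with an estimated correlation). P4hb, which folds collagen, had 0.47 (SE 0.14), and the mitochondrial chaperones Hspd1 and Hspe1 had -0.37 (SE 0.10) and -0.34 (SE 0.10). Of 24 hypoxia-induced genes, 1 rose at 2 d (2 higher and 1 lower adjusted over the list alone). At 7 d 2 rose and 1 fell (2 and 1 adjusted over the list alone), the last being Bnip3, a mitophagy receptor (-0.56, SE 0.13). Of 36 angiogenesis and growth factor genes, 1 rose at 2 d, Angptl4 (2 adjusted over the list alone). At 7 d 6 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.335 with an estimated correlation). The heparin-binding growth factor Ptn rose by 1.38 (SE 0.25) and Vegfb fell by 0.83 (SE 0.17). Of 24 immediate early genes, 2 rose at 2 d, Dusp6 (0.99, SE 0.24) and Sgk1 (0.95, SE 0.18; 4 adjusted over the list alone; adjusted p = 0.283 with an estimated correlation). At 7 d 1 rose, Klf6 (0.68, SE 0.14; 1 adjusted over the list alone; adjusted p = 0.431 with an estimated correlation). Other probe sets gave 0.66 and 0.47 for Dusp6 (adjusted p = 0.153 and 0.487) and 0.42 for Klf6 (adjusted p = 0.156) and did not pass. Of 13 circadian clock genes, 0 were called at 2 d and 2 fell at 7 d (3 adjusted over the list alone; adjusted p = 0.355 with an estimated correlation), Usp2 (-0.92, SE 0.20) and Bhlhe41 (-0.58, SE 0.17).

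Of 25 apoptosis genes, 1 rose at 2 d, Casp1, the protease that matures interleukin-1 (0.85, SE 0.20; 1 adjusted over the list alone). In that list 3 rose and 2 fell at 7 d (5 and 3 adjusted over the list alone). Of 19 interferon-induced genes, 1 rose at 2 d, Ifitm1 (0.91, SE 0.22; 1 adjusted over the list alone), and 1 at 7 d, Irf1 (0.48, SE 0.13; 1 adjusted over the list alone; adjusted p = 0.355 with an estimated correlation). Of 16 antigen presentation genes, 0 were called at 2 d (3 adjusted over the list alone; adjusted p = 0.392 with an estimated correlation) and 1 rose at 7 d, RT1-DMa (0.95, SE 0.24; 1 adjusted over the list alone). Of 15 glucocorticoid-responsive genes, 2 rose at 2 d, Angptl4 and Sgk1 (2 adjusted over the list alone), and 1 fell at 7 d, Klf9 (-0.52, SE 0.14; 1 adjusted over the list alone). With the 2 d sham hearts as control Klf9 had -0.23 and did not pass (adjusted p = 0.25). At 2 d, 0 were called of 20 complement and coagulation genes other than C5ar1 (0.76, SE 0.19; 1 adjusted over the list alone; adjusted p = 0.392 with an estimated correlation). Of 10 adipocyte markers, 0 were called at 2 d and 2 rose and 2 fell at 7 d (2 and 3 adjusted over the list alone), with Scd2, a fatty acid desaturase, at 0.98 (SE 0.20) and the lipase Pnpla2 at -0.72 (SE 0.14). Another probe set of Scd2 gave 0.45 and did not pass (adjusted p = 0.149). Of 9 skeletal muscle markers, 0 were called at 2 d and 2 fell at 7 d (2 adjusted over the list alone; adjusted p = 0.207 with an estimated correlation), Eno3 and Myh1. Of 7 nerve and Schwann cell markers, 0 were called at 2 d (1 adjusted over the list alone) and 2 rose at 7 d, Pmp22 (0.56, SE 0.17) and Cnp (0.50, SE 0.15; 2 adjusted over the list alone); another probe set of Cnp gave 0.63 (adjusted p = 0.0581). Of 7 mesothelial and epicardial markers, 0 were called on either day (4 at 2 d adjusted over the list alone; adjusted p = 0.283 with an estimated correlation). With limma, 0 of 4 red blood cell markers, 0 of 4 lung markers and 0 of 3 sex-linked genes were called on either day; adjusted over the list alone, 1 lung marker was higher at 7 d.

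Some genes differed far more between rats of a group than the median residual SD of 0.204 on the log2 scale. RT1-Bb, a class II histocompatibility gene, had a residual SD of 1.532, with signals of 120 to 5122 over the 12 hearts. Lcn2, lipocalin 2, had 0.931, Spp1 0.870 and Myl7 0.814, the last with signals of 2756 to 9699 among the 7 d sham hearts. The median log2 signal of the tested probe sets was higher in IR than in sham hearts by 0.060 at 2 d and 0.071 at 7 d (exact permutation p = 0.1 each, the smallest possible), which is the shift that median centring takes out.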
